A study of Mus musculus with 2 samples.

How the data were processed

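RNA sequencing was used to profile bone marrow-derived macrophages of wild-type (WT) mice and of mice labelled as knockouts of the gene for SIRPα (SIRPα-KO), both C57BL/6 per the labels. Per the labels' protocols, marrow cells were grown for 5 days in medium conditioned with M-CSF, the growth factor that drives macrophage differentiation. They were then treated for 6 h with interferon-γ at 20 ng/ml and lipopolysaccharide (LPS) at 100 ng/ml, in the presence of a reagent that the labels call mCD47.ex. Cells of 5 mice per genotype were mixed before RNA extraction, so each genotype is represented by 1 library and the mice cannot be told apart. Libraries were made with BGI protocols, per the labels.

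The authors deposited 1 expression table per library, holding a gene number, a symbol, annotation terms and 1 value for each of 16263 genes. The deposited values were taken to be FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), a unit that was inferred from the values because the tables do not name one. The unit rests on the step between low values, which scales with transcript length, and on sums that are not the same in both libraries (444294 in WT and 433460 in SIRPα-KO). The submitters' processing notes name the mm9 genome, R 3.3.3 and DESeq2 without saying what each was used for. The aligner, the counting program and the use of strand are not given in the sources used here. FPKM divides by transcript length and library size, so a few very abundant genes can shift all others, and genes with near-identical copies depend on how shared reads were assigned.

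The depth was estimated from the low values. Among genes with 1 annotated transcript, 65.8% of 1003 low WT values and 64.9% of 1057 low SIRPα-KO values lay within 0.15 of a whole number of reads, against 29.8% and 30.5% when transcript lengths were shuffled between genes. The step corresponded to about 11400000 reads in WT and 11300000 in SIRPα-KO. At this depth 10 reads on a transcript of 2 kb equal 0.445 FPKM in WT and 0.450 FPKM in SIRPα-KO. Whole reads could not be recovered for nearly all genes, so no count test was run.

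The analysis had been laid out for read counts, with a fallback for normalized values that was used here. The ratio of SIRPα-KO to WT was computed per gene as a difference of log2(FPKM + 1), a scale that understates differences of low genes. Genes at 1 FPKM or more in at least 1 library were kept (10092 genes). A gene was called higher or lower when the values with the pseudocount differed at least 2-fold. With 1 library per group there is no replicate error, so no p-value was computed, the calls use no interval, and a call describes these 2 libraries.

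Before the data were examined, 31 gene lists were fixed, covering macrophage activation, signalling, metabolism, stress, other cell types that marrow cultures can hold, and control genes. For each list the median log2 ratio of its kept members was placed among the medians of 10000 random lists of equal size, matched on mean expression in 20 bins. A list is described as standing apart when its median lay outside the central 95% of those medians. The percentile is a description and not a test, because genes are not replicates. By construction, about 1 in 20 lists of randomly drawn genes stands apart. The genes of these lists are related and some lists share members, so the rate by chance is not known for them.

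Named genes followed a rule fixed at the same time. It took Sirpa and Cd47, the 10 genes with the largest ratio in each direction among called genes at 5 FPKM or more in 1 library (leaving out predicted genes without a standard symbol), up to 3 called members per direction from each list, the most abundant member of a list without called members, and 5 sex-linked genes. Some genes that this rule takes are not reported here, and no others were put in their place. Other genes named below were chosen after their values were seen.

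Both steps were tested on simulated data. Reads drawn at the estimated depths with no gene changed gave 20 higher and 28 lower calls among 9894 genes kept, from counting error alone. Of 200 genes changed in simulation, 27.5% were called at a true 2-fold difference, 99.5% at 3-fold and 100% at 4-fold. These genes were drawn only from those with a mean of at least 5 FPKM, so recovery of lower genes was not measured. Of 200 random lists, 5% fell outside the central range, as did 100% of 50 random lists raised by 0.5 on the log2 scale.

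Gene numbers were matched to a RefSeq gene table of the GRCm38 assembly, which held 16211 of them, and transcripts came from GENCODE release 21 for mouse. This assembly is later than mm9, so it was used for chromosome names, neighbours, transcript length, GC content and shared sequence, and no coordinates are given. Genes were compared by the share of their 50-base words that also occur in another gene of the tables. Alternatives were another pseudocount, other filters and fold limits, median-of-ratios scaling, list means, and random lists not matched on expression. Chosen after the data were seen were a trimmed-mean scaling without count weights, the removal of genes sharing at least 50% of their words, the removal of X and Y genes, and a restriction to genes with 1 transcript whose exact 95% interval of the estimated reads excluded equality. Such intervals cover counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9.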

Results

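Transcript levels were measured in 2 libraries of mouse bone marrow-derived macrophages, 1 from WT and 1 from SIRPα-KO mice, each made from the mixed cells of 5 mice. SIRPα is an inhibitory receptor of myeloid cells that binds CD47 on other cells and recruits the phosphatases SHP-1 and SHP-2. The cells had been activated for 6 h with interferon-γ and LPS, which drive the classical (M1) inflammatory state, with mCD47.ex present. The comparison addresses how the transcriptome of activated macrophages differs between WT mice and mice labelled as SIRPα knockouts. The libraries held about 11400000 (WT) and 11300000 (SIRPα-KO) reads, as estimated from the deposited values. With 1 library per group the differences have no replicate check.

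Inflammatory cytokine transcripts went both ways in the SIRPα-KO library: Il6 and Il27 were higher, and Il1a and Osm lower. The scavenger receptor Marco was higher, and the anti-inflammatory cytokine Il10 and the chemokines Ccl3 and Ccl4 were lower. Il6 was at 257 FPKM against 93.6 in WT, Il27 at 633 against 292 and Marco at 415 against 65.8. Il10 was at 7.37 FPKM against 39.6, Ccl3 at 63.5 against 606 and Ccl4 at 54.7 against 620. Genes of cholesterol synthesis had a median above all 10000 random lists. Genes of glycolysis, of alternative (M2) activation and of macrophage identity had medians below the central 95% of random lists. In each of these lists most genes were short of 2-fold. Dendritic cell markers had a median log2 ratio of 0.68 (0.17, inside the central range of random lists, with no filter on low values). Neutrophil markers had a median of -0.64 (mean -0.37). In the main computation, osteoclast markers stood apart below and erythroid markers above. B cell, T and NK cell, mast cell and stromal markers lay inside the central range there. Ribosomal RNA rows made up 0.354% of the FPKM sum in WT and 0.0395% in SIRPα-KO, and the nuclear RNA Malat1 was at 83.7 and 32.9 FPKM. The pools also differed in sex-linked transcripts: Xist was almost confined to WT and 4 Y-linked genes to SIRPα-KO, so genotype and the sex of the mice were not separated.

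Sirpa, the targeted gene (gene number 19261, on chromosome 2), was at 153.9 FPKM in WT and 71.5 FPKM in SIRPα-KO, a 2.15-fold lower level. Its transcript was therefore still present in the library labelled SIRPα-KO. The sources used here do not describe the targeted allele, and a value per gene does not show whether the remaining reads came from an intact transcript. None of its 50-base words (0%) occurred in another of the 15929 genes that had a transcript sequence, and the remaining genes could not be compared. Cd47, the gene for its ligand, was at 142 FPKM in WT and 188 FPKM in SIRPα-KO, a log2 ratio of 0.40.

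Of 10092 genes kept, 346 were higher and 434 lower in SIRPα-KO by at least 2-fold, together 7.73%. Counting error alone gave 20 and 28 such calls in simulation. The median log2 ratio of all kept genes was 0.06, and across genes the log2 values of the libraries had a Pearson correlation of 0.953 (genes are not independent replicates). The plot of one library against the other shows most genes close to equality with a wide margin of called genes on both sides.

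**Figure D1:**
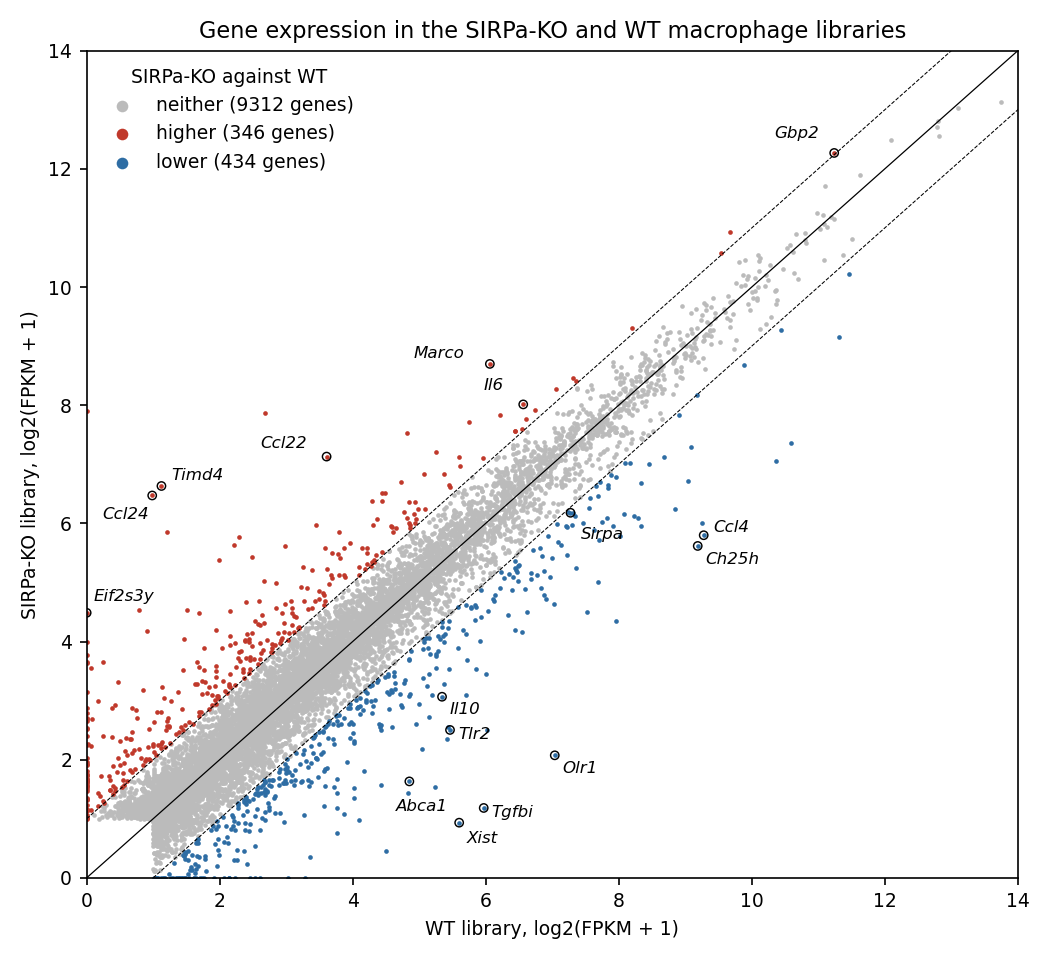
Each point is 1 of 10092 genes, with log2(FPKM + 1) in the WT library on the x axis and in the SIRPα-KO library on the y axis. The 346 genes called higher in SIRPα-KO are red and the 434 called lower are blue, the dashed lines mark a 2-fold difference, and circles mark named genes. Each axis value comes from 1 library, so no error is drawn.

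Among the genes with the largest ratios, Timd4, a receptor for phosphatidylserine on dying cells, was at 98.2 FPKM in SIRPα-KO and 1.18 in WT. Ccl24, a chemokine that attracts eosinophils, was at 87.8 against 0.98 FPKM. Sele, which encodes the adhesion molecule E-selectin, was at 22.2 against 0.73 FPKM, and Pira11, of the paired immunoglobulin-like receptor family, at 56.5 against 1.31 FPKM. Pira11 is uncertain, because its shared sequence could not be measured and the related gene Pira1 shares 86.5% of its words with Pira2. Lower in SIRPα-KO were Olr1, a receptor for oxidized low-density lipoprotein (130 FPKM in WT, 3.21 in SIRPα-KO), Tgfbi, an extracellular matrix protein induced by TGF-β (61.7 and 1.27), and Dusp4, a phosphatase of MAP kinases (21.65 and 0.37). Hivep3 was at 36.8 FPKM in WT and 1.89 in SIRPα-KO, and Spata13 at 27.4 and 1.71. Ch25h, the enzyme that makes 25-hydroxycholesterol, was at 582 FPKM in WT and 48.1 in SIRPα-KO, a log2 ratio of -3.57. Slc28a2, a nucleoside transporter, was at 247 and 19.4 FPKM, and it shares 39.6% of its words with Gm14085, which was at 0.06 and 5.46 FPKM.

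Several of the other large ratios belonged to genes with near-identical copies and are uncertain. Atp6v0c-ps2 was listed at 0 in WT and at 239 FPKM in SIRPα-KO, while its parent gene Atp6v0c was at 408 and 139 FPKM, so that the sum of both was 408 in WT and 378 in SIRPα-KO. Eif3j2 was listed at 0 in WT and at 12.7 FPKM in SIRPα-KO, and its partner Eif3j1 was at 8.73 FPKM in WT and listed at 0 in SIRPα-KO. Rnaset2b was at 64.1 and 4.69 FPKM, whereas the sums with Rnaset2a were 399 and 447 FPKM. Mir5098 was listed at 0 in WT and at 15 FPKM in SIRPα-KO, a value that stands for about 7.97 reads.

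Of the 31 gene lists, 19 stood apart from matched random lists, 7 of them above and 12 below. The plot of list members shows the medians together with the spread of single genes.

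**Figure D2:**
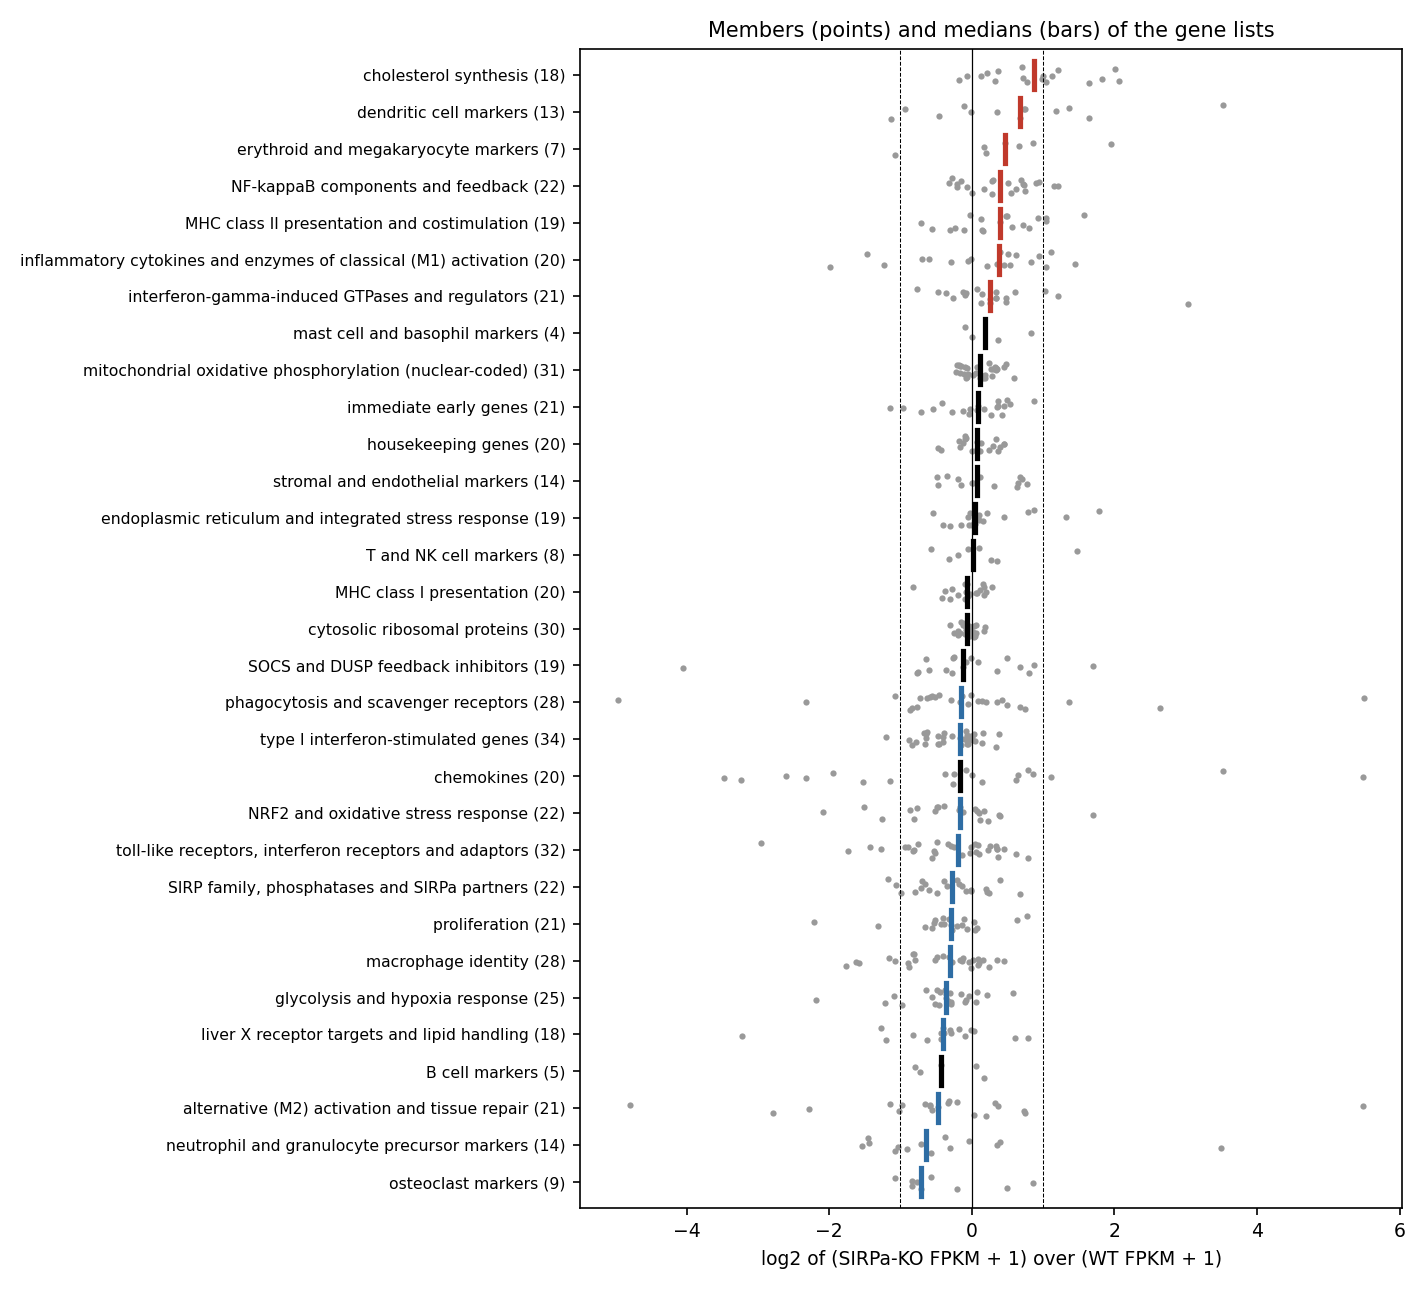
Points are the kept members of each of the 31 gene lists (their number in brackets) on an x axis of the log2 ratio of FPKM + 1 in SIRPα-KO over WT, and bars are list medians, ordered by size. Red and blue bars mark the 7 lists above and the 12 lists below the central 95% of matched random lists, black bars the others, and dashed lines a 2-fold difference; the cholesterol synthesis list has a median of 0.88 and the osteoclast list of -0.71.

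Inflammatory cytokines and enzymes of classical activation had a median log2 ratio of 0.38 over 20 kept members, at the percentile 99.96. Of these, 3 were higher, 3 lower and 14 neither. Higher were Il6, Il27 and Ebi3, the partner chain of interleukin-27 (92.5 FPKM in WT, 192 in SIRPα-KO), which was just under 2-fold with the trimmed-mean scaling. Lower were Il1a (208 and 51.8), Osm (7.75 and 2.17) and Il1rn, the interleukin-1 receptor antagonist (2810 and 1197). Tnf was at 601 and 696 FPKM and Nos2, the inducible nitric oxide synthase, at 1336 and 880 FPKM, both short of 2-fold and named after their values were seen. The mean of the list was 0.11, at the percentile 84.68, inside the central range.

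Chemokines went both ways, with a median of -0.16 at the percentile 3.26, inside the central range, and with 3 of 20 members higher and 7 lower. Ccl24, Ccl22 (11.2 FPKM in WT, 139 in SIRPα-KO) and Cxcl1 (0.66 and 2.57) were higher. Ccl3, Ccl4 and Ccl7 (457 and 74.6) were lower. With random lists not matched on expression, with no filter, or with a minimum of 5 FPKM, this list stood apart below.

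Genes of alternative (M2) activation and tissue repair had a median of -0.48 over 21 members, below all 10000 random lists. Of the members 1 was higher, 5 were lower and 15 neither, and 7 are also in other lists. The higher member was Ccl24. Tgfbi, Pdgfb, a growth factor (13.6 FPKM in WT, 1.12 in SIRPα-KO), and Il10 had the largest ratios among the lower ones. Arg1, another lower member, was at 1.02 FPKM in WT and listed at 0 in SIRPα-KO, at the edge of the filter.

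**Figure D3:**
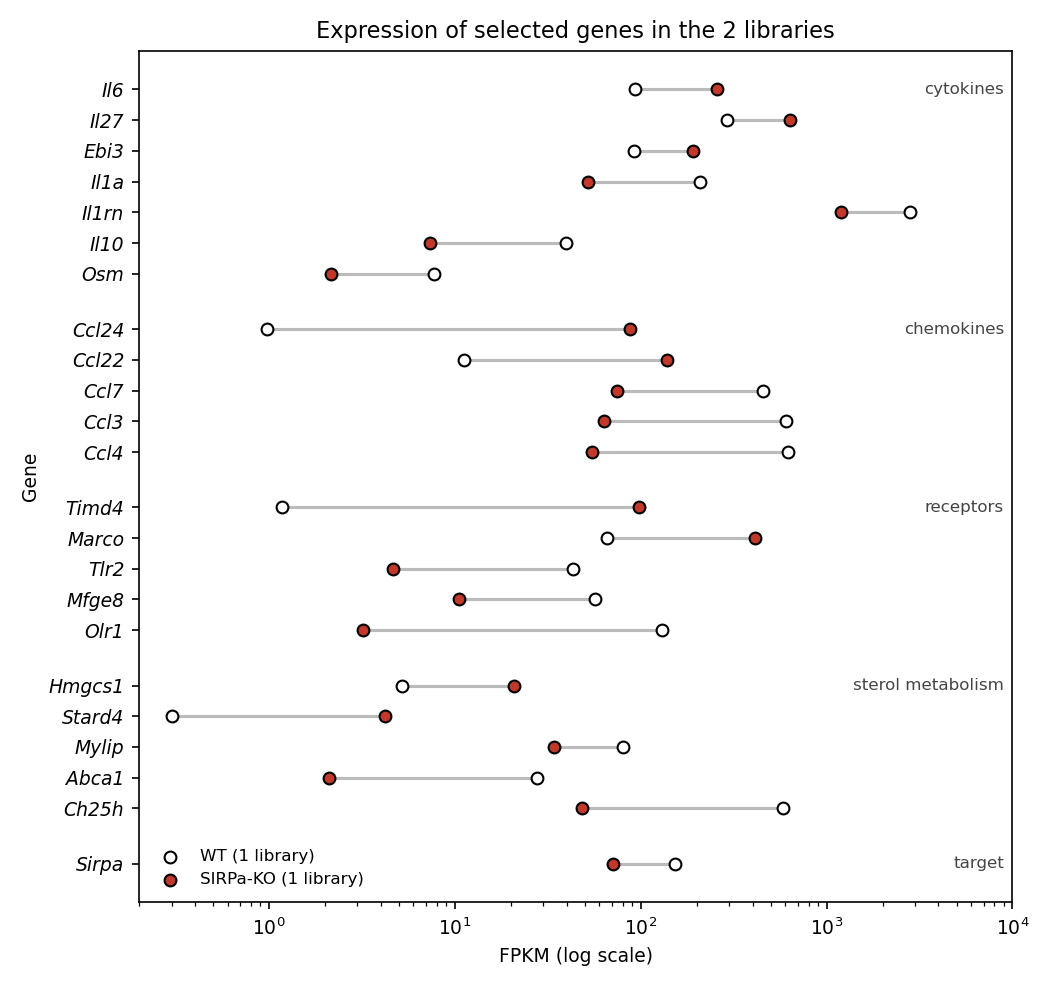
FPKM of selected genes on a logarithmic x axis, with 1 row per gene. Open circles are the WT library and red circles the SIRPα-KO library, joined by a line, without error since each is 1 library. Timd4, Ccl24, Ccl22, Marco, Il6 and Hmgcs1 lie to the right in SIRPα-KO, and Olr1, Ch25h, Abca1, Tlr2, Ccl3, Ccl4 and Il10 lie to the left.

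Type I interferon-stimulated genes and genes induced by interferon-γ stood apart in opposite directions. The type I list had a median of -0.16 over 34 members (percentile 0.51) and a mean of -0.28, with 0 higher and 1 lower. That gene was Ifit3, at 946 FPKM in WT and 411 in SIRPα-KO, which shares 51.2% of its words with I830012O16Rik. The list of interferon-γ-induced GTPases and regulators had a median of 0.26 over 21 members (percentile 99.42), with 3 higher and 0 lower. The higher members were the guanylate-binding proteins Gbp1 (1.84 and 22.2 FPKM), Gbp8 (5.3 and 13.5) and Gbp2 (2417 and 4938). Gbp8 shares 21.2% of its words with Gbp11, and Gbp2 was just under 2-fold with both other scalings. Gbp1 belongs to a pattern, described below, for which the genome of another strain is a candidate explanation. Against random lists not matched on expression the percentile of this list was 97.37, inside the central range.

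MHC class II and costimulation genes had a median of 0.39 over 19 members (percentile 99.99), with 3 higher and 0 lower. Cd74, the invariant chain, was at 741 FPKM in WT and 1521 in SIRPα-KO, the costimulatory ligand Cd80 at 16.1 and 34.0, and H2-DMb2 at 0.91 and 4.7. H2-DMb2 shares 30.8% of its words with H2-DMb1. Cd74, Cd80 and Gbp2 were just under 2-fold with both other scalings, and with no filter on low values the MHC class II list had a median of 0.16 at the percentile 89.94, inside the central range. MHC class I genes had a median of -0.06 over 20 members (percentile 17.98), with 0 higher and 0 lower. B2m, the light chain of class I molecules and the most abundant member, was at 8833 and 8383 FPKM.

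NF-κB components and feedback genes had a median of 0.40 over 22 members (percentile 99.99), with 2 higher and 0 lower. The higher members were Tnip3, an inhibitor of NF-κB signalling (133 FPKM in WT, 308 in SIRPα-KO), and Birc2, a ubiquitin ligase (16.1 and 37.2). Receptors and adaptors of the toll-like and interferon pathways had a median of -0.19 over 32 members (percentile 0.12) and a mean of -0.33, with 0 higher and 4 lower. Tlr2, the receptor for bacterial lipoproteins, was at 43.1 FPKM in WT and 4.67 in SIRPα-KO, the adaptor Traf3 at 15.3 and 3.89, and Tlr13 at 9.35 and 2.86.

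The SIRP family, phosphatases and SIRPα partners other than Sirpa had a median of -0.27 over 22 members (percentile 0.08), or -0.16 with a minimum of 5 FPKM, with 0 higher and 2 lower. Those were Siglec1, a sialic acid-binding receptor (37.8 FPKM in WT, 16.1 in SIRPα-KO), and Inpp5d, which encodes the phosphatase SHIP1 (14.3 and 6.32). SOCS and DUSP feedback inhibitors had a median of -0.13 over 19 members (percentile 3.62), with 1 higher and 1 lower. Dusp5 was at 8.35 and 29.3 FPKM and Dusp4 was the lower member. The list stood apart below with no filter and with a minimum of 5 FPKM.

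Phagocytosis and scavenger receptors had a median of -0.15 over 28 members (percentile 1.06), with 3 higher, 3 lower and 22 neither. Timd4, Marco and Pros1, a bridging protein for dying cells (17.6 FPKM in WT, 47.1 in SIRPα-KO), were higher. Olr1, Mfge8, another bridging protein (56.9 and 10.5), and the inhibitory Fc receptor Fcgr2b (271 and 128.5) were lower. The mean of this list was -0.08, at the percentile 20.78, inside the central range.

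Cholesterol synthesis genes had the highest median of the 31 lists, 0.88 over 18 members, above all 10000 random lists, with 7 higher and 0 lower. The early pathway enzyme Hmgcs1 was at 5.19 FPKM in WT and 20.9 in SIRPα-KO, and Stard4, a sterol carrier, at 0.3 and 4.22. Liver X receptor targets and lipid handling genes had a median of -0.40 over 18 members (percentile 0.02), with 0 higher and 3 lower. The cholesterol exporter Abca1 was at 27.9 and 2.1 FPKM, the lysosomal lipase Lipa at 149 and 60.6, and the ubiquitin ligase Mylip at 80.3 and 34.2.

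Glycolysis and hypoxia genes had a median of -0.35 over 25 members (percentile 0.03), with 0 higher and 3 lower. Pfkfb3, which makes an activator of glycolysis, was at 119 FPKM in WT and 25.3 in SIRPα-KO, the glucose transporter Slc2a1 at 89.0 and 37.6, and hexokinase 2 (Hk2) at 39.7 and 18.1. Nuclear genes of oxidative phosphorylation had a median of 0.11 over 31 members (percentile 64.43), with 0 higher and 0 lower, and Atp5b was at 163 and 205 FPKM.

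NRF2 and oxidative stress genes had a median of -0.17 over 22 members (percentile 1.36) and a mean of -0.29, with 1 higher and 3 lower. Heme oxygenase 1 (Hmox1) was at 117 FPKM in WT and 26.7 in SIRPα-KO, and metallothionein 2 (Mt2) at 147 and 60.8. Glutathione reductase (Gsr) was the higher member, at 12.7 and 43.5. Endoplasmic reticulum and integrated stress genes had a median of 0.04 over 19 members (percentile 43.81) and a mean of 0.23, with 2 higher, Herpud1 (3.47 and 14.3) and Asns (3.74 and 10.8), and 0 lower. Immediate early genes had a median of 0.09 over 21 members (percentile 70.96), with 0 higher and 1 lower, Egr2 (4.25 and 1.38). Proliferation genes had a median of -0.29 over 21 members (percentile 0.24), with 0 higher and 2 lower, Mcm6 (8.62 and 1.08) and Ccne1 (3.6 and 0.84). With a minimum of 5 FPKM only 5 proliferation genes were left and their percentile was 18.54, inside the central range.

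Macrophage identity genes had a median of -0.30 over 28 members (percentile 0.02), with 0 higher and 5 lower. Among these were Csf1r (248 FPKM in WT, 110 in SIRPα-KO) and the transcription factors Cebpa (5.21 and 1.01) and Cebpb (126 and 41.7). Some abundant members were lower but short of 2-fold, such as Cd14 (290 and 164) and Fcgr1 (466 and 325). Others were close to equal, such as Lyz2 (7106 and 7208), C1qa (665 and 663), Emr1 (489 and 519) and Mpeg1 (1056 and 1137). Maf was at 102 and 140. Among markers of other cell types, neutrophil and granulocyte precursor genes had a median of -0.64 over 14 members, below all 10000 random lists, and a mean of -0.37, with 1 higher and 5 lower. Ngp was at 68.8 and 24.7 FPKM, Camp at 5.59 and 1.41 and Elane at 3.36 and 0.5, whereas Chi3l1 was at 3.87 and 53.8. Osteoclast markers had a median of -0.71 over 9 members (percentile 0.02) and a mean of -0.41, with 0 higher and 1 lower, Car2 (22.04 and 9.92).

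Dendritic cell markers had a median of 0.68 over 13 members, above all 10000 random lists, with 4 higher and 1 lower. Ccl22, the chemokine receptor Ccr7 (6.93 FPKM in WT, 23.8 in SIRPα-KO) and Dpp4 (1.32 and 4.95) were higher, and the integrin Itgax (27.7 and 12.1) was lower. Of its members 4 are also in other lists, and with no filter on low values its median was 0.17 at the percentile 95.1, inside the central range. Erythroid and megakaryocyte markers had a median of 0.46 over 7 members (percentile 98.06), with 1 higher, the platelet chemokine Pf4 (37.3 and 148 FPKM), and 1 lower, Car2. The percentile of this list was 96.4 with no filter and 96.69 for the mean, both inside the central range.

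The remaining cell type and control lists lay inside the central range in the main computation. B cell markers had a median of -0.42 over 5 members (percentile 2.72), with 0 called and Blnk at 40.4 and 42.1 FPKM, and stood apart below (percentile 1.11) with a pseudocount of 0.1. T and NK cell markers had a median of 0.02 over 8 members (percentile 42.67), with 1 higher, Ifng (0.52 and 3.24), and 0 lower. Mast cell and basophil markers had a median of 0.19 over 4 members (percentile 73.82), with 0 called and Hdc at 20.1 and 20.1 FPKM. Stromal and endothelial markers had a median of 0.07 over 14 members (percentile 62.79), with 0 called and Kdr at 12.3 and 19.7 FPKM. Housekeeping genes had a median of 0.07 over 20 members (percentile 65.4) and cytosolic ribosomal proteins one of -0.07 over 30 members (percentile 17.5), with 0 called in either list. Rps23, the listed ribosomal protein gene with the highest mean of both libraries, was at 453 and 451 FPKM.

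The sex-linked transcripts differed between the pools. Xist, the RNA that silences an X chromosome in female cells, was at 47.5 FPKM in WT and 0.91 in SIRPα-KO. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were listed at 0 in WT and at 11.6, 21.4 and 2.52 FPKM in SIRPα-KO, and Uty was at 0.05 and 3.69 FPKM. Without the genes of the X and Y chromosomes, 335 genes were higher and 421 lower.

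Genes near Sirpa were compared because a targeted locus can carry flanking sequence of the strain it was made in. Within 5 Mb of Sirpa 75 genes were kept, of which 3 were higher and 4 lower. Their median log2 ratio was 0.09, at the percentile 68.25, and 9.33% of them were called (exact binomial 95% interval 3.84% to 18.3%, treating genes as independent draws) against 7.73% of all genes. Il1a and Siglec1 were among the lower genes of this region.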

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

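The trimmed-mean scaling, the removal of X and Y genes or of genes sharing sequence, and the restriction to genes with 1 transcript and an interval excluding equality were chosen after the data were seen. The counts of genes were within 1.5 times the reported ones under both other scalings, with no filter, with a minimum of 5 FPKM and without X and Y genes or genes sharing sequence. They were 589 higher and 676 lower with a pseudocount of 0.1, 1103 and 1032 at 1.5-fold, and 64 and 72 at 4-fold, as looser or stricter limits must give, and 227 higher among genes with 1 transcript and such an interval, a setting that removes genes in both steps. No called median or called named gene turned sign. With a pseudocount of 0.1 the medians were 1.14 for cholesterol synthesis, -0.80 for neutrophil and -0.88 for B cell markers. With no filter they were 0.16 for MHC class II, -0.33 for M2, 0.74 for cholesterol synthesis, 0.17 for dendritic cell and 0.19 for erythroid markers. With a minimum of 5 FPKM they were -0.32 for chemokines, -0.16 for the SIRP family, -0.26 for SOCS and DUSP genes, -0.14 for proliferation, 0.9955 for cholesterol synthesis, -0.035 for immediate early genes, -0.80 for neutrophil and 0.85 for erythroid markers. That minimum gave no value for B cell, mast cell and stromal markers. Means in place of medians were 0.11 for M1 cytokines, -0.28 for type I interferon genes, -0.33 for toll-like receptors, 0.23 for endoplasmic reticulum stress, -0.29 for NRF2, -0.44 for macrophage identity, -0.37 for neutrophil and -0.41 for osteoclast markers. The cause of these shifts was not tested. The median-of-ratios and trimmed-mean scalings shifted the ratios by at most 0.04 and 0.07. These shifts were enough to turn the sign of the uncalled T and NK cell list under both, and of the endoplasmic reticulum stress list under the latter. Count-weighted TMM factors, a counting interval on every gene and a normalized column set beside counts were planned and not run, since FPKM values alone were used. No paired analysis was possible because each genotype has 1 library. Counting error at the estimated depth gave 20 higher and 28 lower calls in simulation with no gene changed. The recovery of changed genes was simulated only for genes with a mean of at least 5 FPKM and was not split by expression level.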

Other observations

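Gene groups from the annotation terms in the tables were scanned after the data were seen (903 terms of 10 to 200 genes), so the following groups were picked for their ratios. The aminoacyl-tRNA ligases, which charge tRNAs with amino acids, had a median log2 ratio of 0.36 over 35 genes (percentile 99.99), although 1 gene, Lars (6.78 FPKM in WT, 16.8 in SIRPα-KO), passed 2-fold. Aars was at 27.8 and 55.5 FPKM, Gars at 14.8 and 27.0 and Iars at 1.81 and 4.18. Genes of ribonucleoprotein complex biogenesis, many of them ribosome assembly factors, had a median of 0.36 over 26 genes (percentile 99.99), with Gtpbp4 at 7.48 and 22.6 FPKM. Lower were genes of CCR chemokine receptor binding, with a median of -0.67 over 12 genes, 5 of them called: Ccl2 (529 and 104 FPKM), Ccl6 (102 and 34.7), Ccl7 (457 and 74.6), Ccl9 (239 and 61.2) and Ccr2 (17.5 and 7.75).

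Other values in the tables were also singled out after they were seen. Among the 38 rows of ribosomal RNA and its fragments, Rn18s was at 1549 and 163 FPKM. The 10 most abundant genes held 13.5% of the sum in WT and 13.3% in SIRPα-KO. In each of 6 pairs of similar gene copies picked for this, at least 1 member was called, while the sums over each pair differed by less than 2-fold, for example 38.4 and 37.0 FPKM for Trim34a and Trim34b and 213 and 144 FPKM for Tagap and Tagap1.

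In the following patterns, 9 explanations were tested. The tests on sex, on scaling, on H60a and on the region around Sirpa were chosen after the values they use had been seen, and those on shared copies, target genes and length or GC content before. The first pattern is the sex-linked one. Xist in SIRPα-KO was 1.91% of WT and the highest Y-linked gene in WT was 1.36% of its SIRPα-KO level, which is what a female WT pool and a male SIRPα-KO pool would show. Scaling between the libraries is argued against, since the Xist log2 ratio of -4.67 far exceeds the largest shift of 0.07. Of the called genes 3.08% (24 genes) lie on X or Y. These were 20 of 300 kept X genes (6.67%) and 4 of 5 kept Y genes, against 7.73% called among all kept genes. Whether sex contributes to the autosomal differences cannot be told apart from genotype, because each genotype is 1 pool of its own sex pattern.

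H60a, a ligand of the NKG2D receptor that C57BL/6 mice lack, was at 0.05 FPKM in WT and 10.68 FPKM in SIRPα-KO, and Gbp1 was also higher, while H60b (1.14 and 0.1 FPKM) and Raet1d (1 and 0.11 FPKM) had log2 ratios of -0.96 and -0.85, short of 2-fold and resting on few reads (about 13.6 and 14.1 in WT). Genome of a strain other than C57BL/6 in the SIRPα-KO pool is a candidate explanation for this pattern, though the labels give C57BL/6 for both pools and FPKM values cannot show sequence variants. Reads shared between near-identical copies stay open too, because only 3 of the 4 genes had a value, too few for that check. H60a had none, so the 0% found for H60b does not cover words shared with H60a. Gbp1 shared 1.84% of its words, which is the median, and Raet1d 98.9%, with Raet1a. Gbp1 lies on chromosome 3 and H60b and Raet1d on chromosome 10, whereas Sirpa lies on chromosome 2. Strain sequence limited to the region around Sirpa would therefore not change the sequence of these 3 genes, and H60a had no position here. Whether such sequence adds to differences nearby was not decided: the median size of the log2 ratio within 5 Mb lay at the percentile 50.51. Of 28 kept genes that are not in the GRCm38 table, 25% were called, against 7.73% of all kept genes. The exact binomial 95% interval was 10.7% to 44.9%, treating genes as independent draws. The called genes included H60a itself, Pira11 and Pira6 (4.21 and 15.2 FPKM), and also the ribosomal RNA Rn18s and Mir1196.

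The cholesterol synthesis list had a high median, with 7 of its 18 members higher and 11 neither, while Ch25h was lower. For this pattern 3 explanations were tested. Transcript length or GC content as the whole cause is argued against, since the trend over all genes was small (0.803% of the variance) and at most 0.10 for any gene of the list, whose median was 0.88 before and after its removal (percentile 100 after it). Lower oxysterol feedback on SREBP2 targets in general predicted that further targets would be higher, which was not seen: 7 targets outside the list had a median of 0.03 (percentile 47.2) and the highest, Aacs, had a log2 ratio of 0.45, although most of them were below 5 FPKM and the bound they met, the percentile 50, was a narrow one. Lower liver X receptor activity may account for part of the pattern. Its 6 targets outside the list, among them Arl4c (16.2 and 7.88 FPKM) and Apoc2 (35.6 and 18.2), had a median of -0.71 (percentile 0.16). However, 12 of the 31 lists were low and none of the 6 genes passed 2-fold. Within the liver X receptor list, Srebf1 (0.79) and Fasn (0.61) had log2 ratios above 0, opposite to what lower activity predicts. Apoe (-0.09) was near equality. Genotype, sex and strain all remain open as the source, so lower liver X receptor activity is a hypothesis for replicated libraries.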
